A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

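The series applied Break-Seq, a method that labels DNA ends in agarose plugs with biotinylated nucleotides, captures the labelled fragments and sequences them, to budding yeast (Saccharomyces cerevisiae). Cells of a strain with the MEC1 checkpoint kinase gene intact (called WT here) and of the mec1-1 mutant (called mec1 here) were held in G1 with 3 µM alpha factor, the mating pheromone. They were then released into 200 mM hydroxyurea (HU), an inhibitor of ribonucleotide reductase, for 1 h, and some were moved to medium without HU for 1 h of recovery (R). The 13 samples each came with 1 list of peaks. Strain, time point and experiment (A, B, C or Control, used as replicate) were taken from the sample titles, and the way a list was called from the sample descriptions and the names of the processed data they give.

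The lists fall into 9 groups. There were 3 mec1 HU lists (Exp A, Exp B, Control) and 2 WT HU lists (Exp C, Control), each called from its HU library alone per the labels. There were 2 mec1 R lists (Exp A, Exp B) and 1 WT R list (Exp C), in which the recovery library was called against the HU library of the same experiment, so that sites equally broken at both times are left out by construction. In the Control experiment each strain also had 2 lists whose sample titles name other material, mock labelling in 1 case and G1 in the other. Their descriptions name peaks of HU called against the library without biotin and against G1, and they were read that way, so every result given as over mock or over G1 depends on this reading. On it, these lists share the HU library with the list called alone. The last list came from mec1 G1 DNA of Exp A cut in vitro with the restriction enzyme BamHI.

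Per the submitters' processing notes, reads were aligned to the sacCer3 build with tools that include Bowtie2 and BWA 0.6.2, and peaks of the first 7 samples were called with MACS 1.4.1. The notes of the 6 Control samples name BWA, and their labels name MACS with no version. Filters, read lengths and the MACS settings are not given in the sources used here. The deposited files hold a position and a score for each peak. The score is the authors' own value from the peak caller. Its scale is not stated in the files, many peaks share the value 3100, and it was used only to rank or filter peaks within a list. The deposited lists carry no read counts, so the sequencing depth is unknown. A longer list can reflect a deeper library as well as more breaks. Binomial intervals given for shares (exact Clopper-Pearson, 95%) cover counting error only.

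Peaks were read on the 16 nuclear chromosomes, and their positions are given here as 1-based, with 1 added to each deposited start. In 1 file chromosomes had 2-digit names, which were translated. No peak lay elsewhere. Genes came from the RefSeq gene table of the R64 assembly, to which sacCer3 corresponds, with 6431 nuclear genes, of which 6002 code for proteins, 275 for tRNAs and 76 for snoRNAs. As the table has no chromosome lengths, the extent of each chromosome was taken as the furthest end of any gene or peak (12.059 Mb in all). The rDNA region was taken from the ribosomal RNA and spacer genes on chromosome XII. That definition was widened to the whole transcribed unit after the first list of regions had been seen. A chromosome end was the outer 20 kb.

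Each observed overlap was set against 10000 random placements of the peaks on their own chromosomes with lengths kept. Placed peaks could overlap each other, and no region was excluded, which departs from the planned exclusion. Peaks counted as overlapping from 1 bp. Group values are means over lists with the SD. Placement p-values are one-sided (upper) for overlaps between lists and for gene lists and two-sided for features, gene positions and the overlap of R with HU lists. The smallest values that the placements can give are 0.0001 one-sided and 0.0002 two-sided. They measure placement chance for these lists. They do not measure variation between cultures, and nothing in the labels says whether the lists of a group come from independent colonies. Placements were drawn separately for each list, although lists of a group share sites, so a recurring site counts repeatedly. The directions of a pair of lists were also placed separately, although both count the same overlaps. Group p-values are therefore likely too small. Numbers of peaks were compared between strains by an exact permutation test. Differences between groups in excess over placement have 95% intervals from 10000 bootstrap draws over peaks, which cover peak sampling only. Draws were separate for each list, so sites shared by lists of a group likely make these intervals too narrow. Benjamini-Hochberg adjustment ran over 135 gene list tests, 45 feature tests, 27 position tests, 11 overlap tests, 48 group differences and 156 pairs of lists, with an adjusted p of 0.05 as threshold. The p-values of the group differences come from the bootstrap and are not printed, as each group holds 3 lists or fewer.

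The gene lists were fixed before the data were examined, as were the groups, tests, changed settings and the rule for named genes. They hold the DNA damage and HU response, the iron regulon, oxidative stress, heat shock and general stress, cytosolic ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, strongly expressed genes, histones, cell wall proteins and flocculins, the pheromone response, G1/S transcription, hexose and nutrient transport, ergosterol synthesis and subtelomeric families. All members of these 15 lists matched the gene table. Lists of early and late origins matched no entry and were not used here.

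The rule for named genes and regions had 4 parts. The first took the 10 regions with the highest mean score percentile among merged regions present in all lists of a group, or the 10 highest-scoring peaks where a group had 1 list. The second took members of the fixed lists overlapped in at least 2 lists of a group (in the only list of a group of 1), up to 10 by score percentile. The third took up to 8 regions found in all HU lists of a strain and in no HU list of the other strain. The fourth took up to 8 recovery regions found in all R lists of a strain and in none of the other. Regions over rDNA were kept apart. A check of the strain-only HU regions in the Control lists of the other strain over mock and G1 was added after the regions had been seen. Other genes named from the fixed lists were chosen after their values were seen.

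The placement tests of single lists were checked on simulated lists with 1000 placements each. Lists with no signal fell below 0.05 in 1 to 9 of 100 simulations. With 10% of peaks moved onto targets, detection was 89 to 99% for a list like mec1 HU A, 73 to 99% for one like WT HU C and 48 to 79% for one like the WT HU Control list with its 43 peaks. With 20% moved it was 94 to 100%. Lists were simulated 1 at a time with each peak placed on its own. The check therefore does not cover means over lists that share sites, or lists with clustered peaks.

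Results were recomputed with the peaks above each list's median score, a score of at least 100, equal numbers of top peaks, a larger minimum overlap, peaks widened by 500 bp, 200 bp around each midpoint, genome-wide placement, circular shifts, removal of chromosome ends and rDNA, gene windows of 250 and 1000 bp, genes matched on length, and each list left out in turn. BamHI site recall, distances to origins, fork direction, GC content, and centromere, origin and retrotransposon classes need a genome sequence or annotation not used here and were not analysed. Retrotransposon peaks were therefore kept when chromosome ends and rDNA were removed. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.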

Results

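Positions of DNA double-strand breaks were given as 13 peak lists, 12 from WT and mec1 yeast released from G1 into HU and 1 from mec1 G1 DNA cut in vitro with BamHI. The lists called from HU libraries alone held 138 (Exp A), 151 (Exp B) and 265 (Control) peaks in mec1 and 103 (Exp C) and 43 (Control) peaks in WT. Recovery called against HU gave 198 and 209 peaks in mec1 and 137 in WT. Read depth is unknown for all lists. All positions are on sacCer3.

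The first comparison asked how many regions were called after 1 h in HU in the mutant and in WT. The mec1 lists held 185 ± 69.9 peaks (SD, n = 3) and the WT lists 73.0 ± 42.4 (n = 2). By an exact permutation test of all splits (two-sided) p was 0.2, which is the smallest value that 3 lists against 2 can give. Covered length was 666 ± 262 kb in mec1 and 294 ± 262 kb in WT (exact permutation p = 0.2, two-sided). The ratio of peak numbers depended on the experiments compared. It was 1.34 for Exp A over Exp C, 1.47 for Exp B over Exp C and 6.16 within the Control experiment. Covered length differed by 1.03-fold and 1.12-fold between Exp A or B and Exp C and by 8.86-fold within the Control experiment. Without the mec1 Control list the difference in mean peak number was 71.5 instead of 112.

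In mec1 cells the same places were called in separate experiments. Of the 138 peaks of Exp A, 60 overlapped peaks of both other mec1 HU lists, against 7.90 under random placement. Merging the lists gave 350 regions, 60 of them present in all 3. The region with the highest mean score percentile was the left end of chromosome III (positions 1 to 5467). The next was at positions 552716 to 556650 on chromosome VIII over PHO12, which codes for an acid phosphatase, and IMD2, a gene of guanine nucleotide synthesis. Others were at chromosome XII 586305 to 593226 (BUR2 and ADY4 among the genes), chromosome VIII 500036 to 503139 (PPX1, an exopolyphosphatase gene, and SMN1) and chromosome X 20905 to 25650, which holds the hexose transporter gene HXT9 and IMA5. Regions on chromosome XVI at 856764 to 864825 (KRE6, GPH1 and SGV1), chromosome X at 709222 to 714023 (the cell wall genes DAN1 and DAN4), chromosome XII at 30339 to 34388 (YCT1), chromosome XIV at 567676 to 572761 (YNL035C and YNL034W) and chromosome V at 498373 to 505841 (the nucleotide excision repair gene RAD4 and the chromatin remodeller gene CHD1) completed the 10.

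The mean share of mec1 HU peaks overlapped by another mec1 HU list was 51.3% (6 ordered pairs), against 11.2% under placement, a ratio of 4.58. The permutation (random placement) test gave p = 0.0001 one-sided, the smallest the placements can give, also after adjustment over 11 overlap tests. In WT the share was 24.7% over both directions of a single pair of lists, against 4.45%, a ratio of 5.56 with the same smallest p. WT HU lists shared 15 of 131 merged regions. The PHO12 and IMD2 region, which came after the chromosome III end in mec1, was the highest of these in WT (chromosome VIII 553204 to 554907). It was followed by chromosome XVI 508028 to 515627 over RAD1, which codes for a subunit of a repair nuclease, and the SUMO protease gene ULP1, and by chromosome II 403960 to 412211 (SPT7, UBC4, TEC1 and MIS1). Chromosome VIII 293052 to 300787 held the hexose transporter gene HXT5, and chromosome XVI 839074 to 844660 the polyamine transporter gene TPO3. Chromosome IX gave 2 regions, at 352858 to 361512 (INP51 and MPH1) and at 244902 to 252350 (RGI2, VHR1 and the tRNA gene SUP17). Chromosome III gave 2 more, at 161799 to 168588 (PMP1) and 128436 to 135330 (ADY2 and ADP1), and chromosome IV 1, at 325683 to 333134 (BRE1 and BDF2).

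The next comparison set break locations of the strains against each other. WT HU peaks were overlapped by mec1 HU peaks in 29.4% of cases against 11.1% under placement, a ratio of 2.64 (permutation, random placement, p = 0.0001 one-sided, the smallest possible). Overlap within a strain had a geometric mean ratio of 4.82 and overlap between strains 2.12. Of the 10 ways to split the 5 lists into 3 and 2, the real one gave the largest difference (exact permutation p = 0.1 one-sided, the smallest possible). Within mec1 the ratios were 6.66 (Exp A with Exp B), 3.54 (Exp A with Control) and 4.13 (Exp B with Control). The WT pair gave 5.54. Pairs between strains varied widely. The mec1 and WT lists of the Control experiment overlapped at a ratio of 4.27, and mec1 Exp A and Exp B overlapped the WT Control list at 1.42 and 1.14. With WT Exp C the ratios were 2.90 for mec1 Control, 2.28 for Exp A and 1.98 for Exp B. The ratio between strains within the Control experiment lay above those of mec1 Control with mec1 Exp A and Exp B. With 1 pair from a shared experiment, an effect of the experiment was not tested, and the difference cannot be ascribed to strain alone.

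Among the 60 regions in all mec1 HU lists, 51 were in no WT HU list. By score these were led by the BUR2, PPX1, HXT9, GPH1, DAN4, YCT1 and YNL035C regions already given and by chromosome XIV 26001 to 32793, which holds EGT2, a cell wall gene active in early G1, and LEM3. Of the 15 regions in both WT HU lists, 4 were in no mec1 HU list. They lay on chromosome III at the ADY2 and ADP1 genes (128436 to 135330), chromosome XVI at 71758 to 77026 (RPL36B and YAH1), chromosome XIII at 646554 to 653110 (RPL36A) and chromosome XI at 257888 to 261058 (the cell wall gene CWP2). Of these 4, all but the CWP2 region overlapped peaks called from the mec1 Control HU library over mock and over G1, so they are not shown to be specific to WT. Those mec1 lists cover 17.3 and 18.7% of the genome, and chance overlap was not tested for these regions. The overlap is therefore weak evidence that both strains share them. None of the 51 was called in the WT lists over mock or G1, but WT lists cover less of the genome, so absence from them is weak evidence of a difference at any 1 region. A peak over the ribosomal RNA genes at the RDN5-1 and RDN37-2 genes of chromosome XII was called in mec1 Exp A (459089 to 460753), mec1 Exp B (459329 to 460877) and WT Exp C (458959 to 460753), each with a score of 3100.

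**Figure D1:**
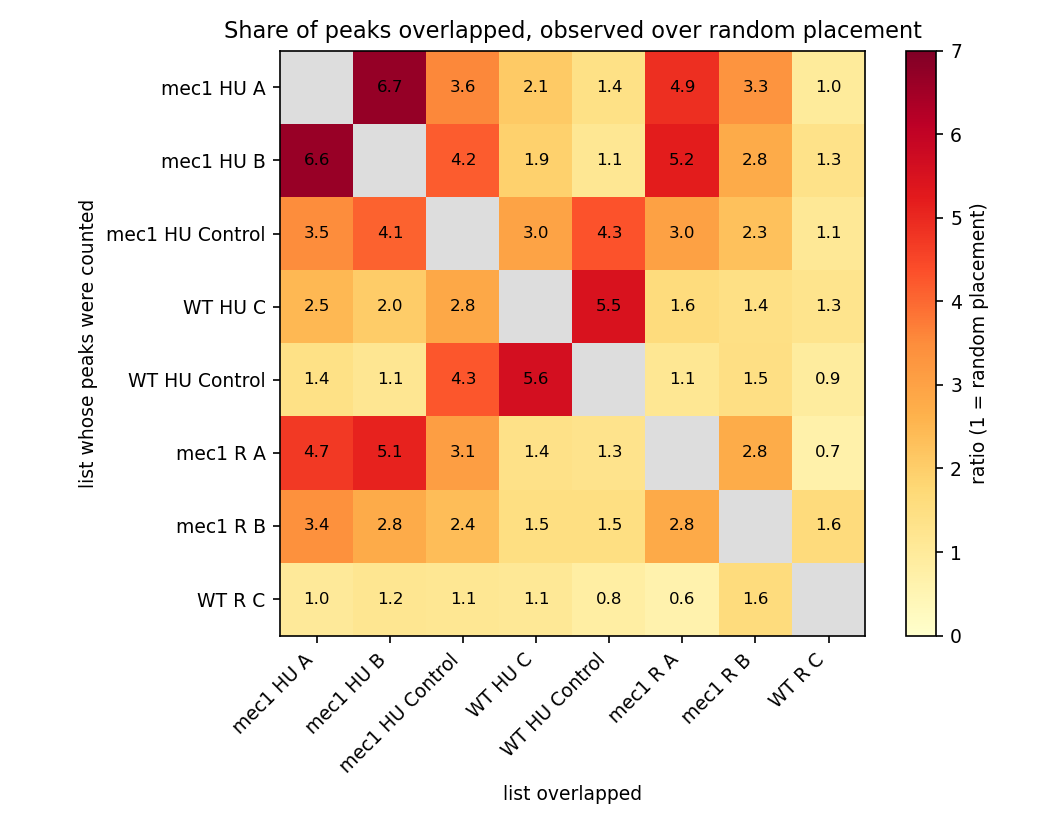
Ratio of the observed share of overlapped peaks to the share under random placement for 8 peak lists, with the list counted on the vertical axis and the list overlapped on the horizontal axis. The mec1 HU Exp A and Exp B lists overlap at a mean ratio of 6.66 and the WT R list lies near 1 with most lists.

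Peaks were then placed relative to annotated features. Chromosome ends, where telomeres and gene families such as PAU, COS and YRF1 lie, took 15.8% ± 3.38 (SD, n = 3) of mec1 HU peaks against 5.89% under placement (permutation adjusted p = 0.0011, two-sided), and each of the 3 lists lay above expectation (14.5, 13.2 and 19.6%). WT HU peaks lay there in 6.11% ± 4.52 of cases (n = 2) against 6.06%. The excess over placement was 9.86 points larger in mec1 than in WT (bootstrap interval 3.99 to 15.2), which passed after adjustment over 48 differences. Within the Control experiment the difference was 10.5 points, with an interval that included 0 (-0.14 to 19.8).

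Transfer RNA genes, short genes read by RNA polymerase III, were overlapped by 13.8% ± 3.28 of mec1 HU peaks (n = 3) against 7.96% (permutation adjusted p = 0.0011, two-sided). Taken singly, the mec1 lists gave permutation p of 0.1447 (Exp A), 0.0081 (Exp B) and 0.0001 (Control), one-sided and unadjusted. In WT HU the share was 21.8% ± 14.4 (n = 2) against 8.05% (permutation adjusted p = 0.0011). The WT value came mostly from Exp C, with 33 of 103 peaks (32.0%), while mec1 Exp B had 20 of 151 (13.2%, counting interval 8.28 to 19.7%). The WT Control list gave 11.6%, and on its own did not pass (permutation adjusted p = 0.368). When each peak was reduced to 200 bp around its midpoint, the tRNA share was below expectation in both strains (0.252 against 0.637% and 0 against 0.649%).

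Small nucleolar RNA genes were overlapped by 0.598% of mec1 HU peaks against 1.90% (permutation adjusted p = 0.0508) and by 4.08% of WT HU peaks against 1.95% (permutation adjusted p = 0.241). Shares of peaks over the rDNA region were 0.462% in mec1 and 0.485% in WT HU, with adjusted p of 0.740 and 1.0 in the permutation (random placement) tests. Nearly all peaks touched a protein-coding gene. The shares lay slightly under expectation, at 96.6 against 98.9% in mec1 HU (permutation adjusted p = 0.002) and 93.4 against 98.4% in WT HU (permutation adjusted p = 0.009). Neither call held without chromosome ends and rDNA, and that of WT HU was also lost with a score of at least 100.

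Midpoints of HU peaks lay inside genes less often than placement gives, although most were inside a gene. They fell there in 55.4% ± 4.23 of mec1 HU peaks (n = 3) against 72.8% under placement and in 54.0% ± 9.12 of WT HU peaks (n = 2) against 72.6% (permutation adjusted p = 0.0009 in both, two-sided). Within 500 bp of the 3′ end of a gene lay 47.7% of mec1 HU midpoints against 39.6% (permutation adjusted p = 0.0012), and within 500 bp of the 5′ end 37.2% against 42.4% (permutation adjusted p = 0.0267). For WT HU these were 45.7 against 39.5% and 45.9 against 42.4%, and neither passed. The 3′ excess of mec1 HU minus that of WT HU was 1.92 points (bootstrap interval -8.00 to 11.5), so it is not shown to be particular to mec1. Taken singly, the mec1 HU lists gave permutation p at 3′ ends of 0.1118 (Exp A), 0.0032 (Exp B) and 0.0071 (Control), one-sided and unadjusted. The WT HU lists gave permutation p of 0.0245 (Exp C, 49.5% of midpoints) and 0.4286 (Control, 41.9%) in the same way. Without WT Exp C the inside-gene share was 60.5% and no longer passed, and the 5′ value of mec1 did not pass without Exp A or without the Control list.

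**Figure D2:**
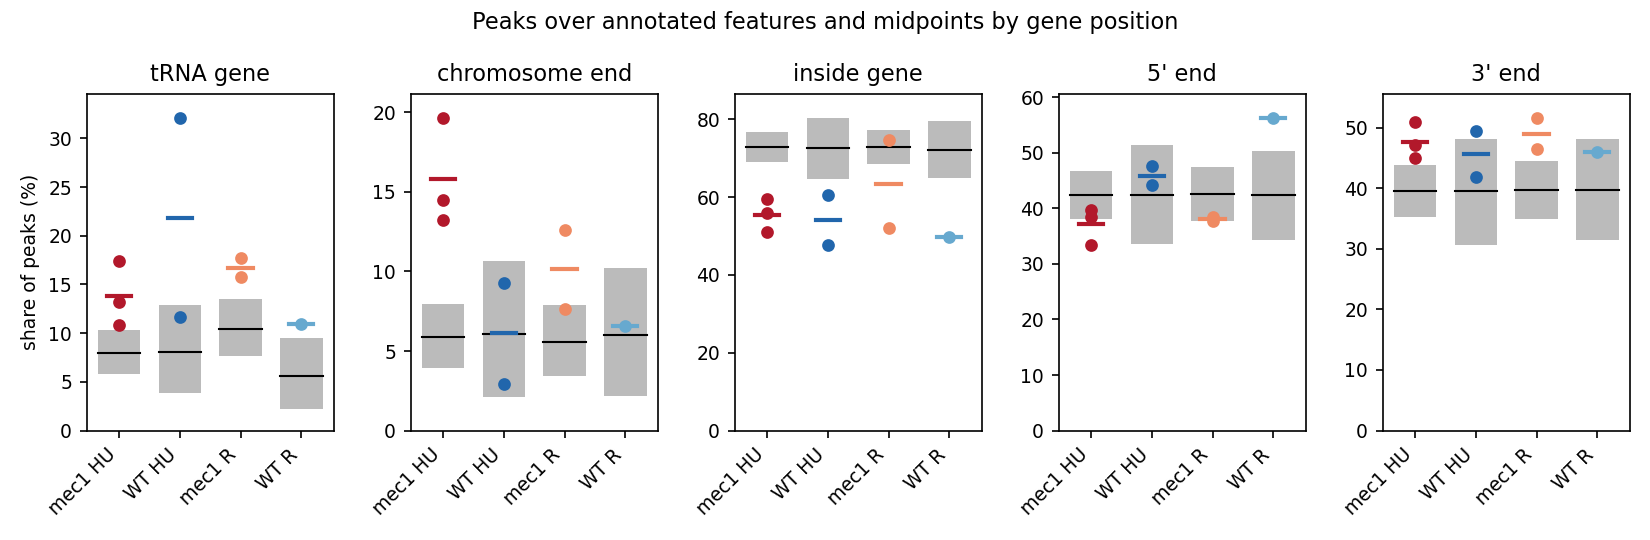
Share of peaks in percent over tRNA genes and chromosome ends, and of peak midpoints inside genes or within 500 bp of gene 5′ or 3′ ends, for 4 groups of lists. Points are single lists, coloured lines their mean, black lines the mean of 10000 random placements and grey bands the central 95% of placements; all 3 mec1 HU lists lie above the band at chromosome ends.

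Genes for nutrient uptake were overlapped by mec1 HU peaks more often than placement gives. Of 49 transporter genes, 9.33 ± 0.577 (SD, n = 3) were overlapped per list against 3.95. MAL31 (maltose permease), PHO87 (phosphate transporter) and GAL2 (galactose permease) were overlapped in all 3 lists. The hexose transporter genes HXT6 and HXT7 and the histidine permease gene HIP1 were overlapped in Exp A and Exp B, and SUL1 (sulfate) and GAP1 (general amino acid permease) in Exp B and Control. HXT6 and HXT7 were reached only at their ends, by peaks that lay mostly between or beside them. The excess depends on whole peaks, as 200 bp around midpoints gave 1.33 genes against 1.51. The subtelomeric families gave 8.00 ± 9.54 of 51 genes against 3.22. COS8 was overlapped in all 3 lists, but most other members, among them PAU and YRF1 genes, only in the Control list.

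These were the 2 of 15 lists that passed in mec1 HU (permutation adjusted p = 0.0068 for each, one-sided). Adjusted over the list alone, 3 passed (p = 0.0009 for transport, 0.0018 for subtelomeric families and 0.0461 for glycolysis in the same permutation test). These group tests count sites shared by the HU lists repeatedly. Taken singly, Exp A, Exp B and Control gave permutation p of 0.0033, 0.0049 and 0.0477 for transport, one-sided and unadjusted. Without the Control list the subtelomeric count was 2.50 against 2.51. Against random genes of matched length neither list kept an adjusted p under the threshold (permutation p = 0.0513 for transport and 0.146 for subtelomeric families).

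Members of other lists recurred in mec1 HU without the list passing. The iron regulon gave 4.33 of 31 genes against 2.18, and FIT1, ARN2 and ENB1, genes for siderophore retention and uptake, were hit in all 3 lists. Glycolysis gave 3.67 of 25 against 1.87, with the hexokinase gene HXK1 in all lists. Cell wall genes gave 5.00 of 46 against 3.84, with DAN4, EGT2 and FIG2 in all lists. G1/S genes gave 4.33 of 38 against 3.02, with the cohesin gene SMC3 in all lists, and the pheromone response gave 3.00 of 31 against 2.63, with the a-factor gene MFA2 in all lists. The DNA damage and HU response list gave 1.67 of 25 against 1.82, with RAD7 in Exp A and Control, DDR48 and RAD53 in Exp B and DDR2 in Control. Ribosomal protein genes gave 7.00 of 138 against 8.65, ribosome biogenesis 2.67 of 42 against 3.53, heat shock 2.67 of 30 against 2.49 and oxidative stress 1.67 of 27 against 1.88. Strongly expressed genes gave 0.667 of 28 against 2.53, histones 0.333 of 11 against 0.666 and ergosterol 0.333 of 24 against 1.51.

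In WT HU no list passed, and 1 of the 15, transport, had an unadjusted permutation p under 0.05. It gave 3.50 of 49 genes against 1.60 (permutation p = 0.048 one-sided, adjusted 0.250 and adjusted over the list alone 0.087). HXT5 and HXT2 were overlapped in both WT lists, and the ribosomal protein gene RPL36A was as well. HXT6 and HXT7 were overlapped in Exp C, at their ends by 1 peak lying mostly between them, and the histone genes HTA2 and HTB2 in the Control list. Whether the strains differ in these gene lists was not tested.

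**Figure D3:**
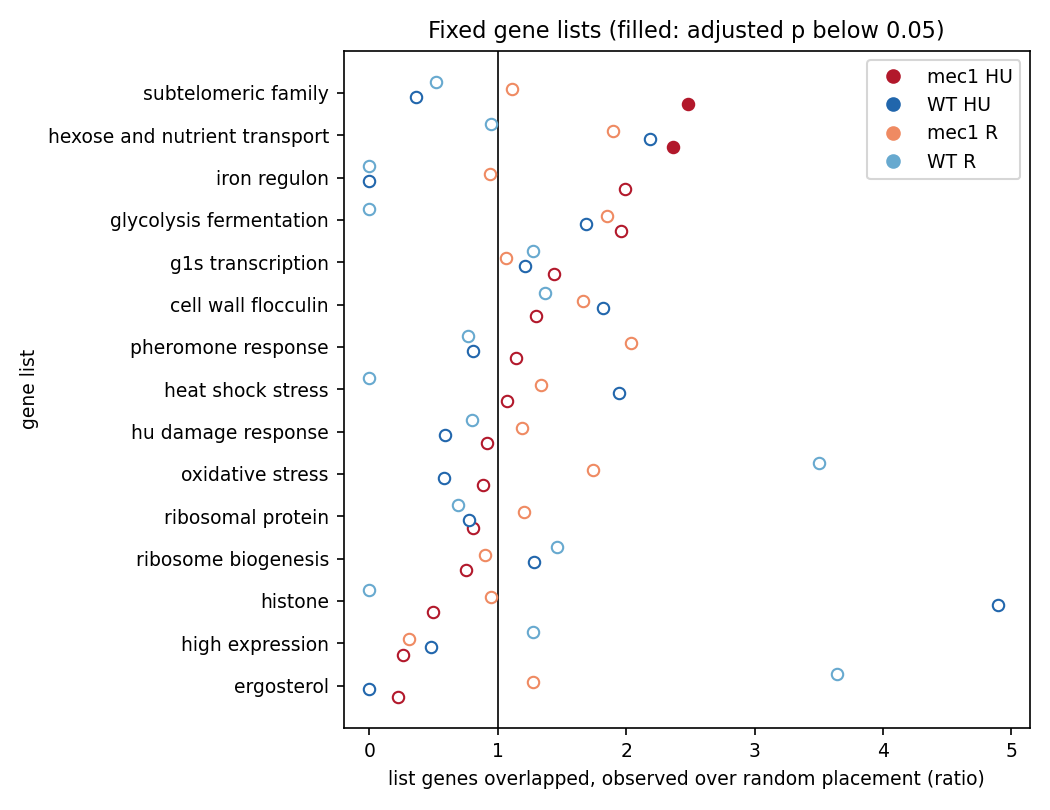
Number of genes of each fixed list overlapped by peaks, as a ratio to random placement on the horizontal axis, for 4 groups of lists. Filled points have an adjusted p under 0.05, which holds for transport (9.33 against 3.95 genes) and subtelomeric families (8.00 against 3.22) in mec1 HU.

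**Figure D4:**
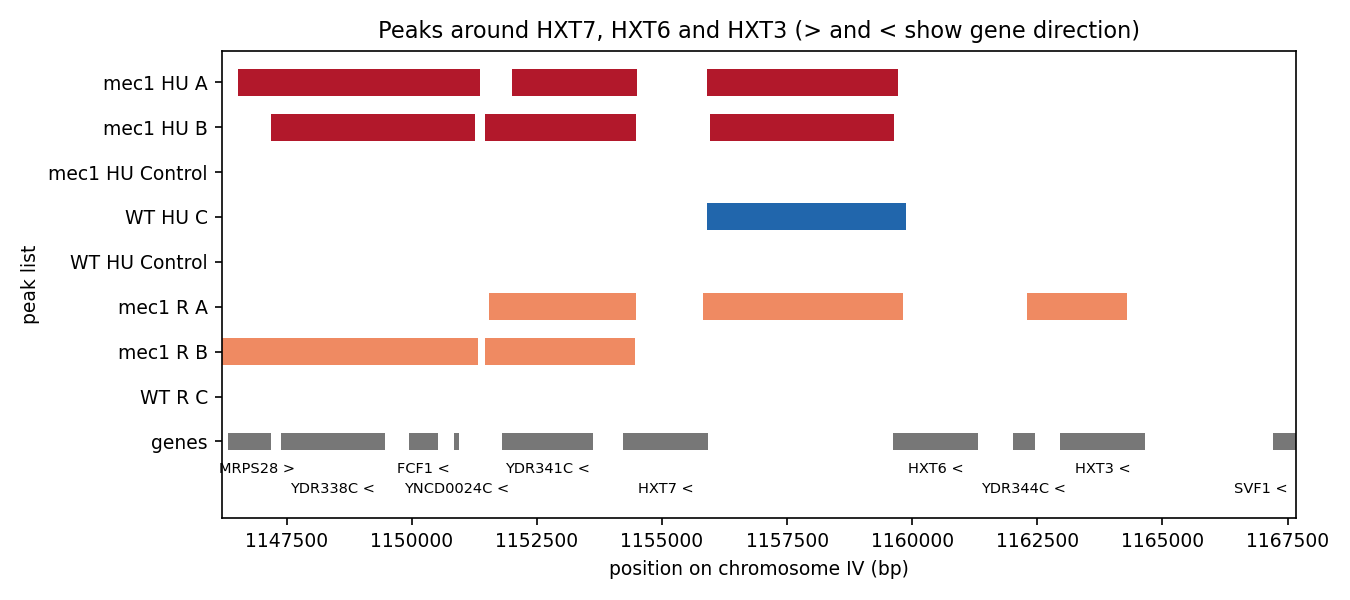
Peaks of 8 lists on chromosome IV around the hexose transporter genes HXT7, HXT6 and HXT3, with position in bp on the horizontal axis and genes in grey. Peaks between HXT7 and HXT6 were called in mec1 HU Exp A and Exp B (for Exp B at 1155951 to 1159639), WT HU Exp C and mec1 R Exp A.

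Recovery lists show where signal stood above the HU library of the same experiment 1 h after HU was removed. In mec1 many recovery peaks lay at places already called in HU. The highest region in both mec1 R lists, chromosome III 190262 to 199049, held PHO87 and the bud site gene BUD5. The next were chromosome VII 1060934 to 1067564 (BIO2 and IMA1), chromosome XIV 567611 to 571823 (YNL035C and YNL034W), chromosome II 320501 to 331523 (QDR3, TCM62 and ZTA1) and chromosome XII 286691 to 292536, with SIC1, which codes for an inhibitor of S phase cyclin-kinase, and GAL2. Chromosome X gave 223642 to 235104, with the glutathione synthesis gene GSH1, and 541252 to 554534, with CDC8 and CBF1. Chromosome XIII 550645 to 558795 held RPL13B and RPS16A, chromosome XVI 856602 to 865095 the glycogen phosphorylase gene GPH1, and chromosome V 130516 to 138943 the transcription factor gene GCN4. At the edge of the rDNA, chromosome XII 448331 to 451608 was a region of its own.

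Of mec1 R peaks, 37.6% overlapped an HU peak of the same experiment against 10.1%, a ratio of 3.71 (permutation, random placement, p = 0.0002 two-sided, the smallest possible). The shares were 46.0% in Exp A and 29.2% in Exp B. In the other direction, 67.4% of the HU peaks of Exp A and 40.4% of those of Exp B were overlapped by the recovery peaks of their experiment. In WT only 6.57% of recovery peaks overlapped HU peaks against 6.16% (permutation p = 0.943, two-sided). In both strains, calling recovery against HU leaves out sites equally broken at both times, so these shares are not the full overlap of break sites.

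The highest WT recovery peaks were at chromosome VI 178992 to 187205, with FAB1 and IGD1, chromosome IX 205907 to 207675 over YIL082W-A, and chromosome IV 891442 to 895611 with the transcription factor genes UPC2, of sterol uptake, and ADR1. Chromosome XIII 249072 to 252125 held the sterol synthesis gene ERG6, chromosome VII 411686 to 414765 RIM8, and chromosome XVI 642835 to 648220 the glutamine synthetase gene GLN1. The remaining 4 held ADE3 (chromosome VII 901786 to 907208), HEM1 and LYS4 (chromosome IV 928221 to 931882), SWI1 (chromosome XVI 519520 to 523557) and LSM7 (chromosome XIV 349275 to 352382). The ERG6 gene was also overlapped in mec1 R Exp B, and the LSM7 peak overlapped a region called in all 3 mec1 HU lists (chromosome XIV 350143 to 354303).

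The mec1 R lists overlapped each other in 44.3% of peaks against 16.0%, a ratio of 2.77 (permutation p = 0.0001 one-sided, the smallest possible). Between strains the share was 10.6% against 9.45% (permutation adjusted p = 0.189, one-sided). That mean joined unlike lists, with 15.4% against 9.57% for Exp B and 5.92% against 9.33% for Exp A. Without Exp A the overlap passed, but that leaves a single pair of lists, whose directions count the same overlaps as if they were independent. By direction, Exp B with WT R passed in the pairwise tests (permutation adjusted p = 0.0199 and 0.0218). Of 88 regions in both mec1 R lists, 85 were in no WT R peak, and 102 of 137 WT R regions were in neither mec1 R list.

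In the mec1 R lists the pheromone-response kinase gene FUS3 and MFA2, the mismatch repair gene MSH6, and the checkpoint kinase gene RAD53 were overlapped in both experiments. So were HXT7 (only at its ends), HXT9, PHO87, GAL2, ADH4, TDH1, COS8 and ARN2. No gene list passed, and 4 had an unadjusted permutation p under 0.05. Transport gave 10.5 of 49 genes against 5.53 (permutation adjusted p = 0.075, and 0.015 adjusted over the list alone, one-sided), the pheromone response 7.00 of 31 against 3.43 (permutation adjusted p = 0.085), glycolysis 5.00 against 2.71 and cell wall genes 8.50 against 5.11. In WT R no list passed either. Ergosterol genes ERG6, ERG3 and ERG26 made 3 of 24 against 0.824 (permutation p = 0.045 one-sided, adjusted 0.250). Ribonucleotide reductase gene RNR2 was the member of the damage and HU response list overlapped in WT R. Other named members were KAR4, SPB1, NSR1, TAT2, RPL2A, RPL29 and UTR2.

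By position, mec1 R peaks overlapped tRNA genes in 16.7% ± 1.33 of cases (n = 2) against 10.4% (permutation adjusted p = 0.0011, two-sided) and chromosome ends in 10.1% ± 3.51 against 5.56% (permutation adjusted p = 0.0045). Without Exp A neither passed. WT R gave 10.9% against 5.60% for tRNA genes (permutation adjusted p = 0.06) and 6.57% against 5.98% for chromosome ends. Midpoints of WT R peaks lay near gene 5′ ends in 56.2% of cases against 42.4% (permutation adjusted p = 0.0025), and those of mec1 R in 38.1% ± 0.414 (n = 2) against 42.6% (permutation adjusted p = 0.102). The excess in mec1 R minus that in WT R was -18.3 points (bootstrap interval -28.1 to -8.70), which passed after adjustment. WT R is 1 list with clustered peaks (42 gaps under 3 kb against 5.70), so its 5′ p-value is likely too small and this interval too narrow. Strain and experiment cannot be told apart here. Near gene 3′ ends lay 49.0% ± 3.61 of mec1 R midpoints (n = 2) against 39.7% (permutation adjusted p = 0.0009, two-sided). Singly, permutation p was 0.0004 (Exp A) and 0.0289 (Exp B), one-sided and unadjusted. WT R gave 46.0% against 39.6% there (permutation adjusted p = 0.224). The share of mec1 R midpoints inside genes was 52.0% in Exp A and 74.6% in Exp B, on opposite sides of the expected 72.9%.

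The Control experiment asked which HU peaks remain when the HU library is set against a mock-labelled or a G1 library, as the sample descriptions, though not the titles, have it. Histone genes stood out in WT. HTA1, HTB1, HTA2, HTB2 and HHT1 were overlapped when HU was called against G1, 5 of 11 against 0.163 (permutation adjusted p = 0.0068, one-sided), while HU over mock gave HTA2 and HTB2. With peaks above the median score the G1 count was 2 and did not pass. In this list 1 of 15 gene lists passed, and glycolysis as well when adjusted over the list alone (TPI1, TDH3, FBA1 and ADH1, 4 against 0.897, permutation p = 0.0288). Over mock none passed, and 2 had an unadjusted permutation p under 0.05. The highest WT peaks in both lists lay on chromosome III at 217932 to 224194 (THR4, PWP2) and chromosome XII at 366864 to 374153, over AHP1, a peroxiredoxin gene, CCW12 and HOG1. They were joined by chromosome XII 507206 to 512378, over CBF5 and RFX1, the repressor gene of the ribonucleotide reductase genes, chromosome I 176994 to 181661 with PAU7, and chromosome III 225512 to 230773 with HCM1.

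In mec1, glycolytic genes gave 14 of 25 against 5.44 over mock and 14 against 5.92 over G1, with ENO2, PGK1, FBA1, PDC1 and ADH1 among them. Subtelomeric families gave 19 of 51 against 8.32 and 9.08. These were the 2 lists that passed over mock (permutation adjusted p = 0.0068 and 0.027) and the 2 that passed over G1 (0.0162 and 0.0289 by the same permutation test), and adjusted over the list alone transport passed too, with 3 lists in each. The highest peaks over mock were on chromosome XVI at 625048 to 633527 (APL4, NTO1) and chromosome XII at 157329 to 165072 (SSK1, NSE1), and over G1 on chromosome X at 375813 to 385024, with the chaperone gene KAR2. With circular shifts the subtelomeric count passed in neither. All 472 mec1 peaks over mock had identical limits in the list over G1, so passing in both is not 2 separate results.

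Called against mock, the mec1 HU library gave 472 peaks and against G1 547, which took in 86.8% and 98.1% of the 265 peaks called alone. In WT there were 60 and 90 peaks, which took in 76.7% and 90.7% of the 43 called alone. All 4 shares were above placement (permutation p = 0.0001 one-sided, the smallest possible), but the lists share their HU library and are not independent. Of the peaks called alone, 230 in mec1 and 33 in WT had identical limits in the list over mock.

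The list from mec1 G1 DNA cut with BamHI shows how peaks of a fixed set of ends are drawn. It held 1296 peaks with a median width of 1306.5 bp, of which 745 had a score of at least 3100. The highest were on chromosome X at 406946 to 409312 (CCT3, a chaperonin gene), chromosome XIII at 720607 to 721917 (MRE11, a double-strand break repair gene) and chromosome XVI at 735198 to 736518 (FHL1). Peak midpoints lay inside genes in 79.8% of cases against 73.0% (permutation adjusted p = 0.0009, two-sided), unlike the HU lists, and tRNA genes were overlapped by 2.24% against 3.27% (permutation adjusted p = 0.0937). HU peaks of mec1 Exp A overlapped BamHI peaks in 58 of 138 cases, against 45.3% under placement, those of Exp B in 79 of 151, against 45.1% (permutation p = 0.0388 one-sided, adjusted 0.068), and those of mec1 Control in 114 of 265, against 45.5%. In WT it was 57 of 103 in Exp C, against 51.2%, and 14 of 43 in Control, against 37.8%. None of the 5 passed. No gene list passed for BamHI, and 2 had an unadjusted permutation p under 0.05. Members with high scores were the histone variant gene HTZ1 and, tied with others at 3100, FLR1, CHS2, HCM1 and SNF3.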

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

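Tests of peaks with the highest scores, of Exp A and B against Exp C, of the number of recovery peaks, of the Exp C library and of peak width were chosen only after the result was seen. The values listed first drew attention because the excess of peaks over random placement differed between groups. At chromosome ends the mec1 excess exceeded that of WT by 9.86 points over all HU lists (interval 3.99 to 15.2) and by 11.1 points between Exp A and B and WT Exp C (5.98 to 16.1). At tRNA genes the excess of mec1 Exp A and B minus that of WT Exp C was -17.3 points (-26.7 to -8.00). Over all HU lists it was -7.92 points, which did not pass after adjustment, and within the Control experiment it lay the other way, at 3.11 points (-8.19 to 13.05). The excess of WT recovery minus that of WT HU in Exp C was -16.2 points (-26.3 to -6.46). The last compares 1 list with 1, and recovery was called against that HU library, which leaves out sites equally strong at both times. How far this lowers the WT recovery value was not tested. In mec1 Exp A and B, called the same way, the tRNA excess was 6.33 points in recovery and 4.23 points in HU. Near gene 5′ ends the excess of mec1 recovery minus that of WT recovery was -18.3 points (-28.1 to -8.70). This sets Exp A and B against 1 WT list, so strain and experiment cannot be told apart. Recovery peaks were clustered, which likely makes this interval too narrow, and no cause was weighed for it. The 2 values for chromosome ends, the -17.3, the -16.2 and the -18.3 points passed after adjustment over 48 differences, against peak sampling alone.

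The ratios of recovery over HU lay on opposite sides of 1 in the strains, but they set lists called against HU beside HU lists called alone. Covered length was 1.99 times (Exp A) and 1.93 times (Exp B) that of HU in mec1 and 0.623 times in WT (Exp C). Median peak width was 1.29 and 1.36 times that of HU in mec1 and 0.329 times in WT. These 6 values come from 2 experiments and 1, and the difference between strains was not tested.

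The excess of mec1 HU peaks at chromosome ends, near genes such as COS8 and ARN2, was weighed first. The chromosome end region of PHO12 and IMD2 was called in all HU lists of both strains. Without peaks over subtelomeric families and rDNA the mec1 excess still exceeded that of WT, by 7.41 points (1.58 to 12.7), against reads shared between copies of those families as the whole cause. With the 40 highest-scoring peaks of each list the difference was 17.4 points (8.04 to 26.5), against an origin in low-scoring peaks, and the 11.1 points of Exp A and B over Exp C argue against the Control experiment as the only source. The removal took out only 3 (Exp A), 4 (Exp B) and 17 (Control) mec1 HU peaks, and kept other genes of chromosome ends, such as PHO12 and IMD2. Reads shared between other repeated sequences there, in or outside the gene table, stay open, as does sequencing depth. An effect of the mutation may remain as a hypothesis.

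The covered length of recovery over HU was weighed second. Calling mode alone moves this measure, since the mec1 Control HU library covered 967 kb alone and 2081 kb over mock, and the WT one 109 and 156 kb, so the mec1 ratios cannot be read as a change from HU to recovery. Keeping peaks with a score of at least 100 gave 0.558 in WT and 2.54 and 2.43 in mec1, so the pattern was kept. Median scores, however, were higher in recovery than in HU in mec1 and lower in recovery in WT. A fixed cut across lists called in different ways can therefore move these ratios apart by itself. It cannot decide what weak peaks near the calling threshold contribute, and that stays open. WT peaks were 1.33 times as many in recovery while covering less, so the number of peaks does not account for it. The WT HU list of Exp C had unusually wide peaks (median 4943 bp, against 2084 bp in the WT Control list), and with 1 WT recovery list that library, calling mode and strain could each contribute and stay open.

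The tRNA excess of WT HU was weighed last. Within WT it was 15.6 points larger in Exp C than in the Control list (2.18 to 28.0), but this restates the shares of 32.0 and 11.6% and sets 1 list against 1 with peak sampling as the only error, so library and strain stay open. Peaks of Exp C wider than the median carried an excess of 40.1 points over placement of the same widths (26.5 to 53.5), and the narrower ones 3.44 points. Placement keeps widths, so the excess of the whole list already showed that width alone is not enough, and this split is no further test. It replaced an earlier one on the difference of wider and narrower peaks (36.6 points, 20.7 to 52.2), which had been read in favour of width but was mistaken for the same reason. What made the Exp C peaks wide stays open, and no biological explanation was tested.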

How the results depend on the processing

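Over 57 results and 472 alternatives, 391 kept direction and side of the threshold, 35 became weaker, 11 stronger, 7 moved and 28 changed direction. All alternatives were planned, but which gene lists were followed singly was decided after a first set of alternatives had been seen, which lowered the number of reversals reported. The other 52 pairs of gene list and group gave 445 alternatives, of which 0 passed and 65 lay on the other side of the expected number. The 18 results that never changed include overlap between mec1 HU lists (ratio 3.55 to 6.89), WT HU lists (4.66 to 7.79), mec1 R lists (2.49 to 3.74), mec1 R and HU (2.77 to 5.57), mec1 and WT HU (1.83 to 3.72), and the mec1 HU excess at chromosome ends. Except where the setting's own construction shows it, the cause was not tested. No paired analysis was possible because only the Control experiment held HU lists of both strains, a single pair whose difference is given on its own, because the R lists were already called against HU, and because the planned fit with the experiment letter as a replicate block needs origin positions not used here. BamHI site recall, origin distance, fork direction and GC content were not run under any setting. Unknown depth limits every comparison of list lengths.

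Reducing peaks to 200 bp around midpoints, with expected values from windows of the same length, turned the tRNA share below expectation in mec1 HU (0.252%), mec1 R (0.505%) and WT HU (0%), and the snoRNA share of WT HU too (0%). It took the protein-coding share of mec1 R past the threshold (74.0%). In mec1 HU it turned the iron (0), glycolysis (0), transport (1.33) and subtelomeric (1.00) counts and left 0 lists past the threshold. The pheromone count of mec1 R (0.5) and the glycolysis counts of mec1 HU over mock (1) and over G1 (1) turned below expectation, and the damage response count of WT HU (0.5) above it.

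With peaks above the median score, the WT overlap of R with HU was 0%, the WT HU snoRNA share 1.92% (both turned), and the protein-coding share of WT R 92.8%, the mec1 HU 5′ share 35.8% and 3′ share 45.8% and the WT R 5′ share 55.1% no longer passed. That setting gave 1 list past the threshold in mec1 R, and a damage response count of 0.5 in WT HU, above expectation. A score of at least 100 gave 1.23% for the WT overlap of R with HU (turned), 93.1% and 93.8% for protein-coding genes in WT HU and WT R (no longer passing), 1 list for mec1 R and 1.33 damage response genes in mec1 HU (turned).

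Without chromosome ends and rDNA the WT overlap of R with HU was 5.47% and the damage response count of mec1 HU 1.67 (both turned). Protein-coding shares of 98.6% (mec1 HU), 96.9% (WT HU) and 96.1% (WT R) and the mec1 HU 5′ share of 39.5% no longer passed, and 1 list passed in mec1 HU. Genes matched on length left 0 lists there. An overlap of at least 0.5 of the shorter peak took the strain overlap of R lists past the threshold (9.97%). Genome-wide placement did so for snoRNA genes in mec1 HU (0.598%) and tRNA genes in WT R (10.9%), and circular shifts for snoRNA genes in mec1 HU (0.598%), while they turned the WT HU share at chromosome ends (6.11%). Windows of 250 bp took the mec1 R 5′ share past the threshold (18.4%) and turned that of WT HU (22.1%), and windows of 1000 bp took the WT HU 3′ share past it (76.4%). Peaks widened by 500 bp turned the WT HU damage response count (1).

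Single gene lists also lost their call while staying above expectation. With peaks above the median score this held for glycolysis (6 and 8) and subtelomeric families (10 and 11) in mec1 HU over mock and over G1, and for histones in WT over G1 (2). With midpoints it held for subtelomeric families over mock and over G1 (5 each) and histones (2), and with circular shifts for subtelomeric families in both (19 each). Glycolysis over G1 lost it with widened peaks (14) and without chromosome ends and rDNA (12). Genes matched on length ended it for transport (9.33) and subtelomeric families (8) in mec1 HU and for subtelomeric families over G1 (19). Lists gaining a call were iron in mec1 HU (3.67, above the median score) and transport in mec1 R (8.5 above the median score, 10 with a score of at least 100).

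Leaving out each list in turn gave ranges of 5.92 to 15.4% for the strain overlap of R lists, 95.9 to 97.6% and 90.7 to 96.1% for protein-coding genes in mec1 and WT HU, 15.8 to 17.7% and 7.66 to 12.6% for tRNA genes and chromosome ends in mec1 R, and 11.6 to 32.0% and 2.91 to 9.30% for the same in WT HU. Shares inside genes ran from 52.0 to 74.6% in mec1 R and 47.6 to 60.5% in WT HU, 5′ shares from 35.9 to 39.1% in mec1 HU and 3′ shares from 46.4 to 51.5% in mec1 R. Damage response counts ran from 1.5 to 2 in mec1 HU and 0 to 1 in WT HU, subtelomeric counts from 2.5 to 11 in mec1 HU, lists past the threshold there from 1 to 2, and the difference in peak number from 71.5 to 142. The mec1 Control list decided the subtelomeric count, which was 2.5 without it, and the lowest difference in peak number.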

Other observations

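Peaks of the Control lists called against another library often came in runs along a chromosome. In the mec1 list over G1, neighbouring peaks on chromosome II at 228149 to 237405 (HTA2 and HTB2), 238065 to 244894 (NTH2 and COQ1) and 245972 to 253509 (UGA2 and FLR1) all had a score of 3100. In WT over mock, chromosome XII gave 507206 to 512378 (CBF5 and RFX1) and 514126 to 519050 (SAM1, an S-adenosylmethionine synthetase gene, and SWI6, a G1/S transcription factor gene). Chromosome I gave 170717 to 175452 (KIN3 and the mitotic exit kinase gene CDC15) and 176994 to 181661 (PAU7), a pair with the same limits in the WT HU Control list called alone, so calling against another library did not create it. These neighbours were noticed after the lists had been seen.

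The tests on close pairs, on calling against another library and on the distance from recovery to HU peaks, as given here, were chosen only after the result was seen, and those on gene orientation were set out before their values were. The close pair result was first read as negative and is read here as undecided. A first version of the distance test took both strains together and was negative. The versions given here give lists and strains separately.

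A hypothesis was that peaks after HU lie within 3 kb of the next peak more often than placement gives. In mec1 HU there were 6 such gaps against 4.78 (Exp A), 8 against 5.73 (Exp B) and 24 against 19.0 (Control), with permutation p of 0.343, 0.214 and 0.1325, one-sided. The 2 WT HU lists held 7 such gaps against 3.12 expected, with permutation p of 0.0432 (Exp C) and 0.423 (Control), one-sided. After adjustment none of the 5 lists called alone passed, and they do not decide it. All 7 lists called against another library passed. In the Control experiment the mec1 HU library gave 3.01 times the expected number over mock (196 gaps against 65.2) and 1.26 times when called alone, and in WT the ratios were 6.91 over mock, 9.02 over G1 and 1.84 alone. As the HU library is the same, calling against another library may account for most of the close pairs, including the 42 of WT recovery against 5.70.

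Another hypothesis was that recovery peaks lie beside the HU peaks of their own experiment. Outside HU peaks, the median distance of WT recovery peaks to the nearest HU peak was 28.5 kb against 38.2 kb under placement (permutation p = 0.0216 two-sided, adjusted over 3 lists 0.0324). In mec1 the mean of the medians was 33.8 kb against 29.5 kb, with 41.2 against 30.2 kb in Exp A (permutation adjusted p = 0.0324, farther than placement) and 26.4 against 28.9 kb in Exp B. WT recovery peaks were clustered (42 gaps under 3 kb against 5.70), as were those of mec1, while placement puts each peak down on its own. The placement ranges are therefore likely too narrow and these p-values too small. Nearness in WT rests on 1 list, and its cause was not tested. In mec1 Exp A lay farther than placement and Exp B inside its range, so neither list showed nearness.

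The last hypotheses concerned the genes around midpoints that lie outside genes. In mec1 HU, 23.6% of such midpoints lay between convergent genes against 15.9% (permutation p = 0.0101 one-sided; 0.121 two-sided after adjustment over 12 tests, which fails the threshold). The share was above placement in each list, at 31.5% in Exp A, 21.1% in Exp B and 18.1% in Control, but these lists share sites. In mec1 R it was 24.6% against 16.1% (32.3% in Exp A and 17.0% in Exp B), and in WT HU 9.67% against 16.0%, none passing after adjustment. Whether the strains differ was not tested, and an excess of breaks between convergent genes in mec1 may be sought in other data. WT recovery midpoints lay between divergent genes in 33.8% of cases against 33.1%, a negative result.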
